A study of Mus musculus with 57 samples.

How the data were processed

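Expression was measured by RNA sequencing in 56 single mouse T helper 2 (Th2) cells. Per the labels' protocols, CD4+ T cells came from the spleens of 8-week-old C57BL/6 mice. They were grown towards the Th2 fate for 5 days with interleukin-4 and an antibody against interferon gamma, received interleukin-2 after 2 days, and were restimulated through CD3 and CD28. Single cells were captured on a Fluidigm C1, a microfluidic device that isolates cells and amplifies their cDNA, per the labels' protocols. The sample titles number the cells within 5 sets, T1 to T5, of 8 cells (T1) or 12 cells each. What the set number stands for is not given in the labels, so it was treated as a possible batch and never as a group. A further sample, a pool of 10000 cells, was not analysed here.

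The deposited values are a score: TPM (transcript abundance scaled to a fixed total per cell) that the authors had rounded to whole numbers, as the column sums of 999202 to 999914 and the whole-number values show. The table held 10565 genes, and each of them reached 5 TPM or more in at least 1 cell. Per the submitters' processing notes, the genome build was mm9 and the tools were FastQC, Bowtie 0.12.2 and Cufflinks; which tool did which step is not given in the sources used here. TPM keeps no sequencing depth, so the depth of each cell is unknown and no counting error could be attached to a level. A value of 0 can stand for a transcript that was lost in capture or amplification, and genes that every cell uses were also listed at 0 in some cells (Tbp was at 1 TPM or more in 28 cells and Sdha in 36). Such values are therefore reported as listed at 0.

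Gene symbols were compared with the gene annotation of GRCm38.p6, which is a later build than mm9, so it gave names and the order of genes and no coordinates. Of the symbols, 9501 were current, 948 were older names and 116 were not matched. The deposited table writes symbols in lower case; they are printed under the same names, older ones included, with the capital letters of the annotation.

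Each cell is 1 library, and no label names separate animals or cultures, so the 56 cells counted as 1 sample. No test between cells was run and no p-value, standard error or number of changed genes was made from them. A gene was detected in a cell at 1 TPM or more. Shares of cells carry an exact Clopper-Pearson 95% interval, which covers counting error only. Cell-to-cell variation was the squared coefficient of variation (CV2, the squared SD over the squared mean of TPM). Its excess was log2 CV2 minus the running median of log2 CV2 over the 101 genes nearest in mean TPM, for the 7871 genes detected in at least 10 cells. An excess above 1 or below -1 was called. Genes above a mean of 2112 TPM shared the same running median, because too few genes lie above them.

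Gene lists (29) and gene pairs (21) were fixed before the data were examined, as were the settings above, most of the alternatives and the rule for named genes. The lists were Th2 cytokines, Th2 regulators and receptors, genes of Th1, Th17, regulatory (Treg) and follicular helper (Tfh) T cells, T cell identity, naive T cells, activation, chemokines, G1/S, G2/M, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, interferon response, chromatin architecture, sterol synthesis, unfolded protein response, immediate early and heat shock genes, p53 and apoptosis, MHC class I, housekeeping and sex-linked genes, and markers of B cells, myeloid cells, mast cells and basophils, CD8 T and NK cells, and erythroid cells and platelets. A list was described where at least 3 members had entered. Its median excess, and the mean Spearman rho over its pairs of genes, were placed as a percentile among 10000 random lists of the same size drawn from the same 20 bins of mean TPM. A percentile of at least 97.5 (for variation also at most 2.5) was called. These percentiles describe these libraries and are not tests. For a pair, rho was placed among 10000 random pairs matched in the same way. Correlations over cells carry no permutation p, because the cells are 1 sample. Fixed pairs are given with Pearson's r of log2(TPM + 1). For the main pairs and scores, values with ranks centred by set, as a partial rho on genes detected, or without the 2 cells farthest from the median are added. These 2 cells were picked by 1 member of each pair only: Il4 (with Il13 or Il10), Ccl3, Il3, Maf or the Th2 cytokine score. Cells extreme only for the other member stayed in. A list score was the mean over its members of z-scored log2(TPM + 1). Neighbouring genes were adjacent in the annotation, did not overlap and did not share a symbol stem.

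Genes were named by the fixed rule. It took the lists of Th2 cytokines, regulators, Th1 and activation genes in full, except that 1 Th1 gene is not reported here. From every other list it took up to 4 members (highest mean, largest and smallest excess, members of fixed pairs). It also took the 15 largest and 10 smallest excess values, the 10 highest means, the 10 highest and 5 lowest rho with the cytokine score, and the 5 genes at each end of the first and second principal components of 500 variable genes. Cd3d, Foxp3, Il17f, Sdha, Tbp and Yy1, the pairs of neighbouring genes, and several genes of the closing section fall outside the rule and were chosen after their values were seen.

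No cell was removed. No doublet caller was run, since such callers need counts; doublets were addressed through marker lists, gene numbers and averages of cells. The check for cells of another type needed 3 markers of 1 list at 10 TPM or more, and at most 1 member of each such list was analysed here, so it could not decide. The sex-linked check needed Y-linked genes that were not analysed here; Xist was at 1 TPM or more in 54 cells. Genes with near-identical copies, such as ribosomal protein genes, Gapdh and Gm-numbered pseudogenes, can exchange reads with them, and their values are uncertain.

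Alternatives chosen in advance were detection above 0 or at 10 TPM or more, leaving out cells with few genes, each set left out, detection in 5 or 20 cells, the SD of log2(TPM + 1) in place of CV2, a running median over 301 genes, TPM rescaled per cell, Pearson's r with pseudocounts of 1, 0.1 and 10, ranks centred by set, and partial rho. Because values are whole numbers, detection above 0 is the same as the main setting, and 0 cells had so few genes as to be left out, so these 2 alternatives moved nothing. The steps were tested on simulated data over 7871 genes. Of 100 genes with CV2 raised 4-fold, 82% were called, and of 100 raised 8-fold, 92% were called, against 4.20% of 7671 others. All 20 simulated lists with a shared factor were called as varying together and 0 of 20 without one were. The simulated genes were otherwise independent, with no unusual cell and nothing that made cells differ in genes detected. These rates are therefore not error rates for the real cells. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.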

Results

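Single-cell transcriptomes were collected from 56 mouse Th2 cells, the CD4+ T helper cells that drive allergic and anti-helminth responses, after 5 days of culture and restimulation through the T cell receptor. The cells form 1 group, so the comparisons are between genes and gene groups over these cells. The median cell had 4743.5 genes at 1 TPM or more (SD over cells 904, range 2679 in T4_3 to 8396 in T3_5). By set, the median was 4694 in T1, 4837 in T2, 4272.5 in T3, 4708 in T4 and 4789.5 in T5. Of all values, 55.4% were 0, and 398 genes were detected in every cell. The median Spearman rho between 2 cells was 0.491, from 0.234 to 0.750, and 0 of 1540 pairs of cells held identical values. Cells T3_2 and T3_5 stood apart. In T3_2 the humanin-like gene Mtrnr2l took 20.1% of all TPM, and its median rho with the other cells was the lowest, at 0.268. T3_5 had 8396 genes, against 6983 in the cell with the next most.

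**Figure D1:**
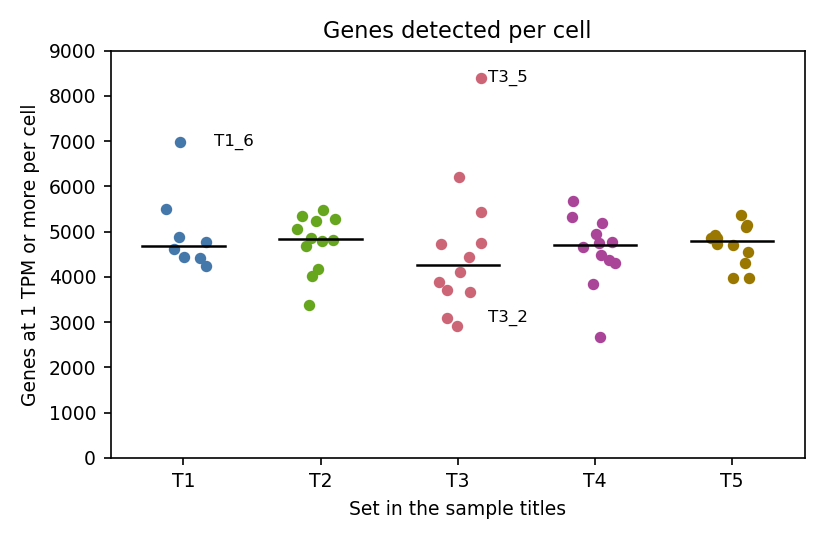
Number of genes at 1 TPM or more in each of the 56 cells (vertical axis, genes) by set T1 to T5 (horizontal axis), with a line at each set's median. Set medians lie between 4272.5 and 4837 genes, and cell T3_5 stands above all others with 8396.

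To describe the identity of the cells, levels of T cell, Th2 and other lineage genes were compared. Gata3, the master regulator of Th2 cells, was detected in 56 of 56 cells at a mean of 904 TPM (SD 514), and the Th2 gene Ecm1, which promotes their exit from lymph nodes, was also in all cells at 1894 TPM (SD 1761). The T cell receptor component Cd3d was in 56 cells at 1357 TPM (SD 738), Cd2 in 56 at 1685 TPM and Cd3e in 56 at 100.7 TPM, while Cd4 was low, with a mean of 47.4 TPM in 37 cells. The highest means belonged to Penk, the precursor of enkephalin peptides (30727 TPM, SD 24832), Actb (13891), the CCR8 ligand Ccl1 (11866), the proteoglycan Srgn (11567), the costimulatory receptor Tnfrsf4, known as OX40 (9962), B2m (9886), the cytokine Il3 (6874), Tmsb4x (6839), Hsp90ab1 (6575) and Rps14 (5920). For Il3 and Ccl1 the median cell held far less than the mean, 503.5 and 3925 TPM.

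Other Th2 transcription factors and receptors were detected in fewer cells or at lower levels. Among them, Irf4 (158 TPM) was detected in 53 cells, the chemokine receptor Ccr8 (375) in 52, Batf (588) in 48, the interleukin-4 signal transducer Stat6 (155) in 46, Junb (22.8) in 44 and Maf (155) in 38. Lower numbers were found for Il4ra (26.6 TPM, 35 cells), Pparg (87.4, 29), Ccr4 (62.6, 27), the interleukin-33 receptor Il1rl1 (15.8, 24), Gfi1 (35.1, 23), Gpr44 (5.64, 18) and Nfil3 (19.5, 13). Rbpj, the Notch effector, was in all 56 cells at 74.6 TPM.

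Genes of other T helper fates were mostly low. Among Th1 genes, Il18rap was in 33 cells, Il12rb1 in 32, Runx3 in 30 and Stat4 in 15. Cxcr3 was in 10, Il12rb2 in 8, Il18r1 in 4 and Eomes in 3. The highest mean of these 8 genes was 32.4 TPM (Il12rb1). Cell T1_2 held 44.8% of the Il12rb1 total, so this ranking rests in part on 1 cell. Of the Th17 list, Il17f was at 1 TPM or more in 1 cell, T3_5, Il1r1 in 15 and Ahr in 28. The Treg factor Foxp3 was in 9 cells (16.1%, 95% interval 7.62 to 28.3) at a mean of 2.61 TPM, whereas Folr4 from the same list was in 50 cells at 457 TPM. Of the Tfh list, the inhibitory receptor Pdcd1 was in 35 cells at 183 TPM, and Bcl6 was in 17 cells at 1.91 TPM. The markers of other cell types analysed here were Cd74 (32 cells, mean 69.9 TPM), Cpa3 (5 cells), Alas2 (2 cells) and Cd8b1 (1 cell, T3_5); no myeloid marker was analysed here.

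To ask how evenly effector cytokines were expressed, the share of cells with each was compared. Il4, the defining Th2 cytokine, was detected in 54 of 56 cells (96.4%, 95% interval 87.7 to 99.6), Il13, which acts on epithelium and mucus, in 31 (55.4%, 41.5 to 68.7), and Il5, the eosinophil growth factor, in 14 (25%, 14.4 to 38.4). At this threshold the 3 intervals do not overlap. All shares are of the same 56 cells, so overlap of separate intervals, here or at 10 TPM, is no test of a difference. Mean levels were 1954 TPM for Il4, 348 for Il5 and 50.2 for Il13, and the highest single cells held 26918, 3732 and 536 TPM. All 31 cells with Il13 also had Il4, against 29.9 if the 2 genes were independent. With Il4 in 54 of 56 cells, the overlap could hardly differ from that number, so it says little about co-expression. In 10 cells all 3 cytokines were detected, and in 2 cells none was. At 10 TPM or more the shares were 85.7% for Il4, 33.9% for Il13 (21.8 to 47.8) and 17.9% for Il5 (8.91 to 30.4), and the intervals of Il13 and Il5 overlap.

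At 1 TPM or more, some of the remaining cytokines were found in nearly every cell and others in a minority. The hematopoietic growth factors Il3 and Csf2 were each in 55 cells (6874 and 3038 TPM), Il24 in 54 (1515), and the anti-inflammatory cytokine Il10 in 52 (1519), as was the epidermal growth factor family member Areg (222). The itch cytokine Il31 was in 24 cells (549 TPM), and Il6 (89.2 TPM) and the mast cell growth factor Il9 (257 TPM) were in 13 each. Cell T4_5 held 63.6% of the Il9 total and cell T5_6 38.8% of the Il6 total. At 10 TPM or more, Areg was in 32 cells and Il3 in 41. The median cell had 8 of the 11 Th2 cytokines, and cells ranged from 3 to 11.

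**Figure D2:**
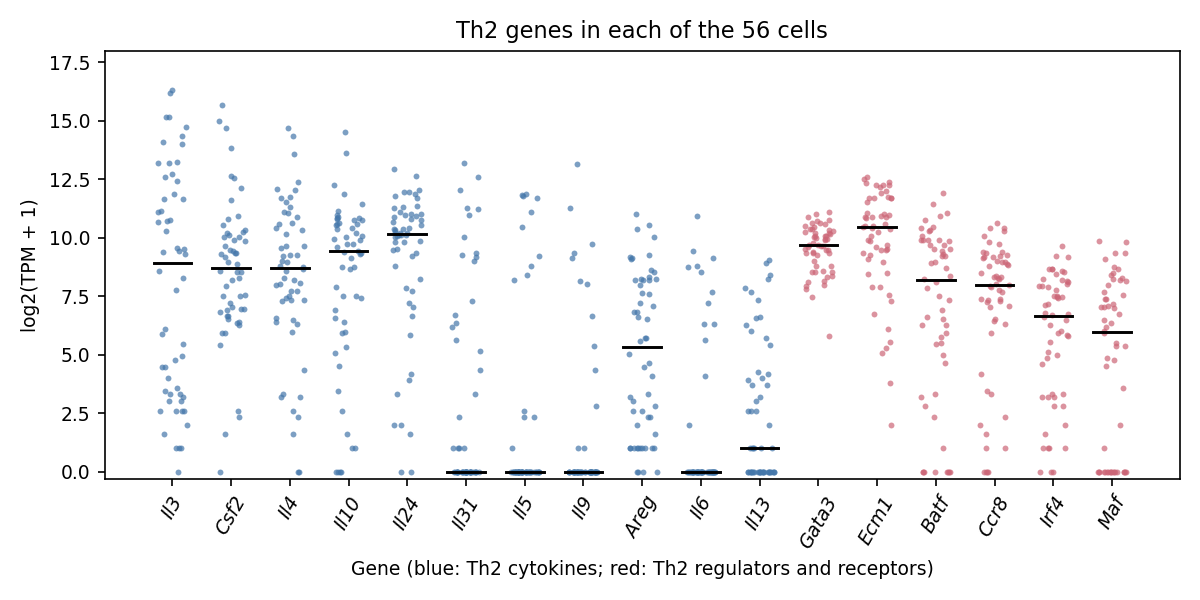
Level of Th2 cytokine and regulator genes in each of the 56 cells, as log2(TPM + 1) on the vertical axis, 1 point per cell, with a line at the median. Gata3 was in all cells with a median of 818 TPM, while the median of Il5 was 0 TPM.

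To find which genes differed most between cells, variation was compared with that of genes of like mean. Th2 cytokines, chemokines and activation genes were more variable than matched genes, and ribosomal protein genes less. Variation was taken over all 56 cells and was not computed within sets. Differences between sets, which may be batches, are therefore part of it. Of 11 Th2 cytokines, 10 had excess variation above 1, with a median excess of 3.87 on the log2 scale and the exception of Il13 (0.57). The values were 5.04 for Csf2, 4.57 for Il9, 4.53 for Il4, 4.42 for Il3, 4.08 for Il10, 3.87 for Il31, 3.11 for Il5, 2.15 for Il6, 1.76 for Il24 and 1.38 for Areg. Of the chemokines, which recruit other leukocytes, 7 of 7 were above 1 (median 3.53), among them Ccl5 (6.26), Ccl3 (4.16), Ccl4 (4.12) and Ccl1 (2.38). The value of Ccl5 rests on cell T2_8 and is 1.89 without it.

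Among activation genes, 14 of 23 were above 1 (median 1.12). The T cell growth factor Il2 (5.10) was in 39 cells, with a median of 2.5 TPM and a highest value of 31888. Others above 1 were the inhibitory receptor Ctla4 (2.95), Nr4a1 (2.53), Nfkbid (2.17), the B cell help ligand Cd40lg (1.92), Zbtb32 (1.55), Tnf (1.48), Nr4a3 (1.48), the early activation antigen Cd69 (1.48), Myc (1.34), Tnfsf11 (1.16), Tnfrsf18 (1.12), Tnfrsf9 (1.08) and Icos (1.06). The NF-kB inhibitor Nfkbia (1459 TPM in 56 cells), Il2ra (660 in 56) and Cd44 (350 in 56) had excess values of 0.00, 0.26 and -0.39. Tnfsf8 (1483 TPM), which lay just under the threshold, was not called, nor were Lta (0.94), Tnfrsf4 (0.38), Nr4a2 (0.32), Egr1 (0.30) and Egr2 (-0.18), and Egr3 (6 cells) and Irf8 (9 cells) did not enter. Without each gene's highest cell, the excess was 0.60 for Nr4a1, -0.18 for Nr4a3, 0.49 for Myc and 0.90 for Tnfrsf9.

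These 3 lists each lay at the 100th percentile of matched random lists. G2/M genes were at percentile 99.7 (median 0.45; 10 of 47 above 1, led by Fam64a at 2.07, and 4 below -1), but at 91.2 without set T2 and 93.4 without T4. The Tfh list rested on 3 genes (median 1.35, percentile 98.8) and was called in 8 of 13 alternatives. Of the 75 ribosomal protein genes, 61 were below -1 (median -1.54, percentile 0), with Rpl21 (-4.20) lowest. Oxidative phosphorylation genes were at percentile 0.470 (median -0.31; 16 of 72 below -1, Atp5l at -2.98 lowest), but at 4.74, outside the threshold, for the 65 members with no pseudogene copy named in the annotation (median -0.22). Chromatin architecture genes, which include cohesin and its partners, were at 0.580 (median -0.73), with 6 of 16 below -1, Med1 at -2.33 lowest. The 2 above 1 were Smc3 at 2.00, or 0.10 without its highest cell, T3_2, and Yy1 at 1.04. Without T3 or T5 the list's percentile was 3.42 or 3.24, and with the SD of log2(TPM + 1) it was 3.04, all outside the threshold.

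The other 14 described lists lay between the thresholds in the main setting. Among these, the percentiles of Th1 genes (97.3), Th2 regulators (94.2), unfolded protein response (94.0), interferon response (91.0), G1/S genes (86.6), MHC class I (78.5) and Treg genes (72.0) were the highest. Within the Th1 list, the excess was 1.43 for Cxcr3, 1.05 for Stat4, 0.98 for Il12rb1, 0.87 for Il18rap and -1.36 for Runx3, and the list's percentile ranged from 19.1 to 99.4 over the alternatives. Its median excess was 0.98, and -0.21 without each gene's highest cell. Within the regulators, 4 of 16 were above 1, Ecm1 (1.75), Batf (1.64), Ccr4 (1.14) and Nfil3 (1.10), while Stat6 was at 0.89, Pparg at 0.77, Ccr8 at 0.33, Maf at 0.15, Gata3 at -0.27, Irf4 at -0.56 and Rbpj at -2.52. Without the highest cell, Nfil3 was at -0.09 and Ccr4 at 0.84. In the Th1 list, Cxcr3 was then at 1.26, Stat4 at 0.55, Il18rap at -0.21, Il12rb1 at -0.53 and Runx3 at -0.84. T cell identity lay at 67.1, glycolysis at 63.0, immediate early and heat shock genes at 61.2, sterol synthesis at 57.6, p53 and apoptosis at 52.8, naive T cell genes at 44.5 and housekeeping genes at 4.67. Some of these passed a threshold under an alternative. Housekeeping genes were at 2.34 without T2, 2.28 with the SD of log2(TPM + 1), 1.31 with a wider running median and 0.990 with TPM rescaled per cell. Interferon response genes were at 97.7 without T1 and 97.6 without T4, G1/S genes at 97.7 with the SD of log2(TPM + 1), and immediate early and heat shock genes at 97.7 with that SD and 97.9 with TPM rescaled per cell.

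**Figure D3:**
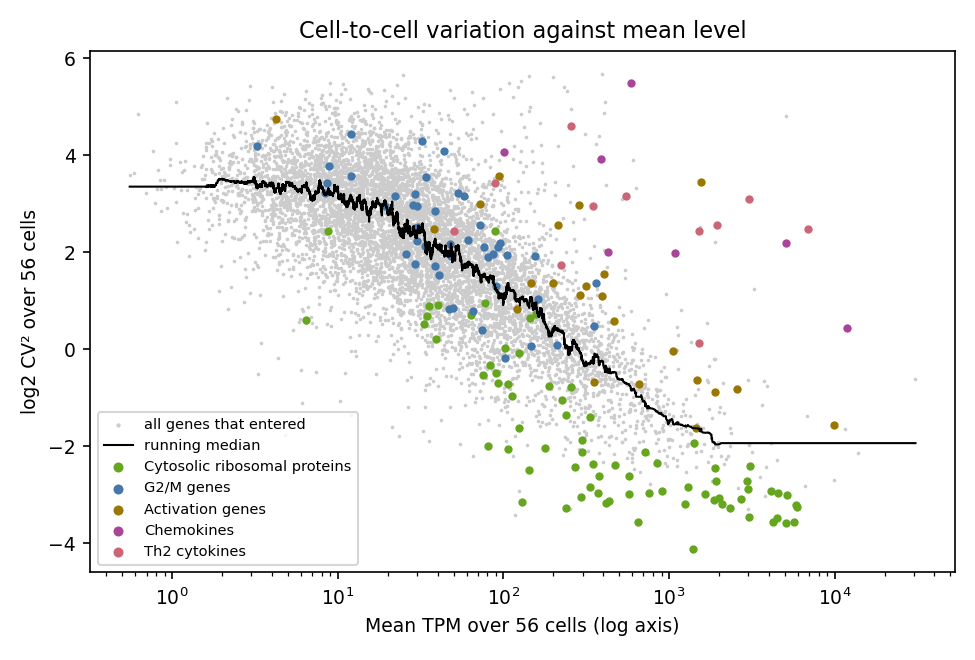
Squared coefficient of variation of TPM over cells (vertical axis, log2) against mean TPM (horizontal axis, log scale) for 7871 genes, 1 point per gene, with the running median as a line and 5 gene lists in colour. Th2 cytokines lie above the line, at a median excess of 3.87, and ribosomal protein genes below it, at -1.54.

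In all, 1033 of 7871 genes (13.1%) were above 1 and 1186 below -1. The number above 1 was 660 with detection in at least 20 cells, a filter that also lets fewer genes enter. With the SD of log2(TPM + 1) in place of CV2 it was 95. There, 1 is a difference in SD and not in log2 CV2, so 95 cannot be set against 1033. The 15 largest excess values belonged to Mtrnr2l (6.74), Ccl5, 5730408K05Rik (5.91), the leukotriene enzyme Lta4h (5.44), Fbxw5 (5.25), the splicing kinase Clk2 (5.22), Siva1 (5.21), Grina (5.18), Il2, Csf2, St3gal1 (4.92), Abcf2 (4.75), Tomm34 (4.73), Cdk11b (4.71) and Nqo2 (4.70). Of these 15, 12 had their highest value in cell T3_2, and of these 12 only Lta4h (1.27), Fbxw5 (1.95) and Grina (1.80) were above 1 without their highest cell. Without each gene's highest cell, 743 genes were above 1, of which 502 were among the 1033. The 10 smallest values belonged to Gm13498 (-5.10), Gm4987 (-4.87), Gm6402 (-4.55), Gm16379 (-4.54), Gm11968 (-4.51), Gm6788 (-4.45), Gm6900 (-4.28), Rpl21, Fam158a (-4.19) and the RNA-binding protein Khsrp (-4.11). Of these 10, 6 are pseudogenes in the annotation, so their values are uncertain next to near-identical parent genes.

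To ask which groups of genes varied together over cells, pairwise correlations within each list were compared with those of matched lists. G2/M genes were the most tightly linked (mean rho 0.379, against 0.046 in matched lists), with the proliferation markers Mki67 and Top2a at rho 0.74. G1/S genes followed (0.279; replication helicase genes Mcm2 and Mcm5 at 0.34), then chemokines (0.209) and interferon response genes (0.197). Th2 cytokines varied together with a mean rho of 0.181, against 0.041 in matched lists, and kept 0.209 with ranks centred by set and 0.122 as a partial rho. Ribosomal protein (0.165) and oxidative phosphorylation genes (0.098) also lay at the 100th percentile. The median cell had 23 of 49 G2/M genes at 1 TPM or more, and cells ranged from 5 to 46.

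In total, 14 of 22 lists were called as varying together. With ranks centred by set the number was also 14, with MHC class I genes (98.3) in place of activation genes, and as partial rho it was 16, with MHC class I genes (99.6) and Th2 regulators (99.99) added. The others called were p53 and apoptosis (0.133), sterol synthesis (0.110), glycolysis (0.099), housekeeping (0.097), T cell identity (0.095), the unfolded protein response (0.092) and activation genes (0.073). Several of these calls were lost with 1 set or cell left out. Activation genes were at percentile 98.3, but at 92.7 with ranks centred by set and at 96.3, 97.3 and 95.1 without T1, T2 and T4. Housekeeping genes were at 98.3, but at 94.4, 93.0 and 95.5 without T2, T3 and T4 and at 90.1 without cell T3_2. Without T5, p53 and apoptosis genes fell to 85.0 and T cell identity to 85.1; sterol synthesis was at 88.5 without T1 and the unfolded protein response at 97.2 without T2. MHC class I (97.4), Th2 regulators (96.1), Treg (84.9), Tfh (84.6), naive T cell (67.2), immediate early and heat shock (56.5), Th1 (48.1) and chromatin architecture genes (3.82) were not called in the main setting. MHC class I genes were called without T2 (98.3), T3 (99.0) or T5 (99.0) and, just at the threshold, without cell T3_5, and Th2 regulators without T4 (98.9). With Pearson's r of log2(TPM + 1) the percentile was 84.7 for Th2 cytokines, 92.4 for chemokines, 76.9 for the unfolded protein response, 58.4 for T cell identity and 45.3 for activation genes. Without cell T3_2 as well, these were called except T cell identity (96.2), while glycolysis was at 96.9 and housekeeping genes at 74.4.

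**Figure D4:**
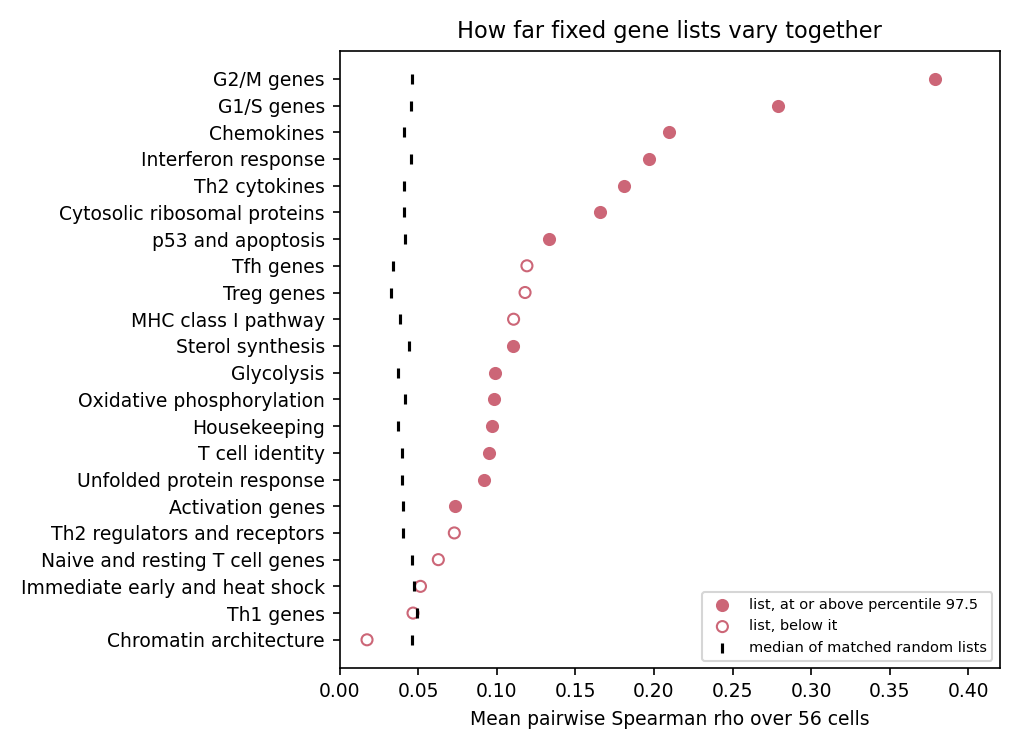
Mean pairwise Spearman rho within each of 22 gene lists (horizontal axis) over the 56 cells, beside the median of matched random lists. Filled points mark the 14 lists called. G2/M genes lie farthest to the right at 0.379, and Th2 cytokines are at 0.181.

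Of the 21 fixed pairs, 19 were analysed here. Il4 and Il13, neighbours in the Th2 cytokine locus, had a rho of 0.27 (Pearson r 0.27; percentile 95.7 of matched pairs), 0.29 with ranks centred by set, 0.24 without the 2 farthest cells and 0.17 as a partial rho. Within sets T1 to T5 the rho was -0.25, 0.30, 0.23, 0.44 and 0.46. It stayed below the upper threshold for the percentile in all 15 alternatives run. The chemokines Ccl3 and Ccl4 had a rho of 0.60 (r 0.65), Il4 and Il10 0.49 (r 0.49), the neighbours Il3 and Csf2 0.44 (r 0.43), and Il4 and its activator Maf 0.34 (r 0.34), all above that threshold. Without the 2 farthest cells, r was 0.59, 0.45, 0.34 and 0.30. As a partial rho, the percentile of Maf and Il4 was 94.8. Within sets T1 to T5 the rho of Maf and Il4 was -0.02, -0.10, 0.58, 0.63 and 0.44. That of Il3 and Csf2 was 0.26, 0.73, 0.65, 0.36 and 0.12. For Il4 and Il10 it was 0.19, 0.56, 0.59, 0.29 and 0.55. Ccl3 and Ccl4 had 0.73, 0.70, 0.57 and 0.62 in T1 to T4 and no defined rho in T5. Mki67 with Top2a (r 0.72) and Mcm2 with Mcm5 (r 0.35) also passed the upper threshold over all cells.

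The other pairs lay within the range of matched pairs. The correlation (rho) was 0.29 for Il4 and Il5 (r 0.22), 0.27 for Il4 and Il24 (r 0.18), 0.21 for Cd3e and Cd4 (r 0.19), 0.19 for Il5 and Il13 (r 0.19), and 0.05 for Il10 and Il24 (r -0.03). The regulator Gata3 had a rho of 0.18 with Il4 (r 0.19), -0.03 with Il5 (r -0.05) and -0.05 with Il13 (r -0.02). Rad50, the housekeeping gene that lies in the Th2 locus, had 0.05 with Il13 (r 0.03) and -0.09 with Il5 (r -0.06). Il2 had -0.13 with Il4 (r -0.11) and -0.26 with its receptor chain Il2ra, the lowest of the 19 (percentile 2.54; r -0.17).

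To relate cytokine output to cycling and activation, list scores were correlated over cells. The Th2 cytokine score correlated most with the chemokine score (rho 0.58, r 0.57) and the activation score (rho 0.55, r 0.51), and less with the G2/M score (rho 0.33, r 0.34). As partial rho on the number of genes detected, these were 0.49, 0.40 and 0.06; with ranks centred by set they were 0.61, 0.56 and 0.34. Without the 2 farthest cells they were 0.56, 0.51 and 0.31. The cytokine score itself had a rho of 0.53 with the number of genes detected, and 0.05 with the score of Th2 regulators. The activation and G2/M scores had a rho of 0.06 (partial -0.26). Of the 231 pairs of list scores, glycolysis and oxidative phosphorylation had 0.66 (partial 0.44), interferon response and MHC class I 0.61 (partial 0.60), and G1/S and G2/M 0.58 (partial 0.44).

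Single genes were then ranked by rho with the Th2 cytokine score. The highest were Tctex1d4 (0.55), Ccdc22 (0.55), the mitotic kinesin Kif15 (0.53), Shcbp1 (0.53), the branched-chain amino acid enzyme Bcat1 (0.53), the actin-severing protein Gsn (0.53), the kinase Map3k8 (0.52), Zc3h12c (0.52), Cdk17 (0.52) and Hnrnph2 (0.51). The lowest were Rbm10 (-0.45), Scrib (-0.41), Rpl14 (-0.39), Bc018507 (-0.39) and Rps20 (-0.39). As partial rho on genes detected, the 10 highest lay between 0.34 (Shcbp1) and 0.47 (Gsn) and the 5 lowest between -0.59 (Rbm10) and -0.27 (Rps20); with ranks centred by set, they lay between 0.52 and 0.57 and between -0.46 and -0.39. In 100 shuffles of the score, the highest rho had a median of 0.48 and reached 0.64, and the lowest had a median of -0.47, so none of these 15 genes lay outside the range of the shuffles. Above the median of the shuffles lay 23 of 7860 genes.

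To ask whether neighbours in the genome vary together, 2933 adjacent pairs of genes were compared with matched random pairs. Their mean rho was 0.0551, against 0.0433 in matched pairs (100th percentile), and 0.0210 against 0.00946 as a partial rho. The highest pairs were Apex1 and Tmem55b (0.99), 1110008F13Rik and Sla2 (0.91), and Pbk and Esco2 (0.70); Ctla4 and Icos, adjacent costimulation genes, had 0.51. These genes were singled out after their values were seen. The annotation is of a later build than the one used for the TPM values, so pairs that overlapped in the earlier models could share reads.

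Levels were also compared between sets, since a set may be a batch. The median of Il10 was 57.5, 1212.5, 247.5, 659 and 1517 TPM in sets T1 to T5, and that of Il3 was 2267.5, 44, 684, 1171.5 and 10 TPM. Medians of Il4 were closer, at 333.5, 707, 230.5, 358 and 437.5 TPM. The growth factor Il2 had a median of 231.5 TPM in T2 and of 3, 2, 8 and 1.5 in T1, T3, T4 and T5. Il5 was in 1, 1, 4, 3 and 5 cells, and Il13 in 6, 7, 5, 7 and 6. The median G2/M score was highest in T5 (0.371) and lowest in T1 (-0.439). With 8 to 12 cells per set and no replicate sets, none of these differences was tested.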

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

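The alternatives without cell T3_2 (alone or with Pearson's r), without cell T3_5, without each gene's highest cell, and without neighbouring pairs of rho above 0.6 were chosen after the results were seen. At 10 TPM or more, the median cell had 3383.5 genes, 85.7% of cells had Il4, 33.9% had Il13 and 19 had both; higher thresholds drop low values by construction. Genes above the threshold of excess variation numbered 660 with detection in at least 20 cells, where fewer genes enter. With the SD of log2(TPM + 1) 95 genes were above 1, but there 1 is a difference in SD. That is an unlike threshold, so 95 cannot be set against the other numbers. Over the other alternatives the number was 743 to 1309, the latter with detection in at least 5 cells, where more genes enter. With each set left out it was 840 to 951. With Pearson's r and pseudocounts of 1, 0.1 and 10, 9 lists varied together each time, against 11 with a pseudocount of 1 and without cell T3_2. Activation genes then fell to percentiles of 45.3 (pseudocount 1) and 26.5 (0.1), below the middle of matched lists, and T cell identity to 42.1 (0.1); with a pseudocount of 1 and without T3_2, activation genes were called again and T cell identity was at 96.2. The unfolded protein response was at 76.9, 55.5 and 95.95 with pseudocounts of 1, 0.1 and 10, and glycolysis at 97.2 (10). Th2 cytokines were at 84.7, 77.5 and 93.9, but at 100 with a pseudocount of 1 and without T3_2. The rho of the cytokine and G2/M scores was 0.0573 as a partial rho on genes detected, which removes the part shared with gene number. Excess variation changed sign for single genes. With each set left out, it was lowest without T3 and ranged from -0.0574 to 5.91 for 5730408K05Rik, from -0.17 to 5.35 for Clk2, from -0.96 to 4.89 for St3gal1 and from -0.90 to 4.85 for Tomm34. Without T3_2 alone it was -0.35, -0.52, -1.32 and -1.06 for these genes and -0.0406 for Siva1 and -0.0444 for Cdk11b. Without each gene's highest cell it was -0.26 for Clk2, -0.83 for St3gal1, -0.78 for Tomm34, -0.0900 for Nfil3 and -0.18 for Nr4a3, and rescaling TPM per cell gave 0.18 for Gm11968, where the cause was not tested. Over all alternatives run for each, Il4 and Il13 rho was 0.174 to 0.321, 4 to 6 lists were more variable and 2 to 4 less, and the neighbouring genes lay at percentiles of 99.87 to 100. Of the other comparisons of named genes with an alternative, 945 gave the same call, 36 lost it and 17 gained it. For the variation of lists the numbers were 279, 10 and 13, and for their co-variation 284, 29 and 8. The alternative without cells of few genes removed 0 cells. Its 79 results for genes, 22 for list variation and 22 for co-variation were therefore the same by construction. No paired analysis was possible because only 1 group has values. Unknown depth limits every statement on genes listed at 0.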

Other observations

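The tests below were chosen after the results were seen, except those on a single cell left out and on 3 to 5 cells in 1 capture, and except partial rho and ranks centred by set, which were chosen in advance as settings; the genes in the next paragraph were also picked after their values were seen, apart from those named by the principal components.

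Single genes outside the fixed lists also differed between cells. Granzyme B (Gzmb), a protease of cytotoxic granules, was in 49 cells at a mean of 3241 TPM (excess variation 3.18), the residency-linked receptor Cxcr6 in 51 at 1353 TPM (1.74), and the decoy interleukin-1 receptor Il1r2 in 39 at 954 TPM (2.52). Neurotensin (Nts), a neuropeptide, was in 45 cells with a mean of 1885 and a median of 7.5 TPM (4.14). The matrix metalloproteinase Mmp10 was in 48 cells at 1538 TPM (4.22). Cyp11a1, the first enzyme of steroid hormone synthesis, was in 51 cells at 1115 TPM (2.01), and Inhba, which encodes a subunit of activin, in 55 at 1691 TPM (2.27). Without the highest cell of each gene, the excess was 3.28 for Gzmb, 1.80 for Cxcr6, 2.60 for Il1r2, 4.12 for Nts, 4.21 for Mmp10, 2.01 for Cyp11a1 and 2.34 for Inhba.

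The first principal component of the 500 most variable genes held 6.03% of their variance. It set cells with Ccl4, Il3, Ccl1, Cd9 and Ccl3 against cells with Ctla4, AW112010, Batf, Trat1 and Glrx, and its rho was 0.809 with the chemokine score and 0.579 with the activation score; Ccl4, Ccl1 and Ccl3 are members of the chemokine score, so part of the former is built in. The rho with the number of genes detected was 0.475 for the first component and 0.458 for the second. The second (5.09%) set Gzmb, Il1r2, AW112010, Il10 and Cxcr6 against Snora52, Wdr5, Pno1, Clk2 and Arnt2. Cell T3_2 carried 15.1% of the squared weight of the first and 38.05% of the second, so the second rests in part on 1 cell.

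Cell T3_2 also differed in common transcripts. Of 555 genes detected in all other cells, 157 were listed at 0 in it, and the median ratio of these genes to their median over the others was 0.0489, against 0.685 to 1.19 in the other cells. It had 3096 genes, and 573 of them at 100 TPM or more. It held the highest value of 115 of the genes with excess variation.

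Th2 cytokine genes varied together over cells (mean rho 0.181). The tests argue against 3 technical explanations of the whole pattern. As a partial rho on genes detected the list stayed at percentile 99.98, and with ranks centred by set at 100. With each cell left out in turn its lowest percentile was 99.99 (mean rho 0.160 to 0.188), but 1 cell has little weight in ranks. With Pearson's r and pseudocounts of 1, 0.1 and 10 the list was at 84.7, 77.5 and 93.9 and was not called. With a pseudocount of 1 and without cell T3_2 it was at 100, so that call depended on 1 cell. Part of the rho may still come from capture efficiency, since the partial rho was 0.122. A shared response of some cells to restimulation is a hypothesis, and no biological explanation was tested, because the cells form 1 group.

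Cell T3_5 had 8396 genes, and more than 1 cell in 1 capture is a candidate explanation. Of 1485 averages of 2 other cells, 0 had as many genes (highest 8029). For averages of 3, 4 and 5 cells, 0 of these numbers gave both its genes at 1 TPM and its 1584 genes at 100 TPM within the middle 95% of 1000 averages, although 1 average of 5 cells had as many genes. T3_5 held the highest value of only 5 of 7871 genes, the fewest of the 56 cells (next 19), as averaging over several cells would give, and averages of rounded TPM are not mixed libraries, so several cells stay open. A more deeply sequenced library stays open too, since 1584 lies both within the 573 to 1957 of the other cells and within the middle 95% of averages of 2 cells (1417 to 1929); no biological explanation was tested.

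The low variation of ribosomal protein and oxidative phosphorylation genes could come from reads shared with pseudogene copies, which average over genes. For the 16 ribosomal members with no copy named in the annotation the median excess was -1.21 (percentile 0). For the 25 with a mean of at least 1000 TPM it was -1.25 (percentile 0). The 10 of these below the flat end of the running median had -1.22 (percentile 0.01). Named copies were those whose symbol is the parent's with the ending -ps, so Gm-numbered copies were not counted. A high mean does not exclude shared reads either, so these values cannot decide and shared reads stay open. Members with named copies were lower, at -1.61, but their median mean was 270 TPM, against 2510 TPM for those with none. Members with a mean below 1000 TPM had -1.89, so copies and level cannot be told apart here. For oxidative phosphorylation, the 65 members with no named copy had -0.22 and a percentile of 4.74, against -1.63 for the 7 with copies. Shared reads stay open there too. No biological explanation was tested.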
